A study of Homo sapiens with 9 samples.

How the data were processed

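U2OS, a human osteosarcoma cell line, was profiled on oligonucleotide expression arrays in 3 groups of 3 samples: cells carrying a non-targeting control shRNA, here called shControl, and cells carrying either of 2 shRNAs directed at BAP1, here called shBAP1 #1 and shBAP1 #2. BAP1 is a nuclear deubiquitinase and tumour suppressor. Per the labels' protocols, shRNA plasmids were introduced by lipid transfection, transfected cells were enriched with puromycin, and the cultures were arrested at the border of G1 and S phase with thymidine before RNA was purified, converted to biotin-labelled cRNA and hybridised. Group and replicate number were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

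The deposited values are log2 expression values per probe set after robust multi-array averaging (RMA), per the submitters' processing notes, which give no version of the tool. RMA corrects background, forces the same intensity distribution on every array and summarises the probes of a set, so a shift of all transcripts in 1 direction is removed and changes of dim probe sets are compressed. The table holds 54675 probe sets for 9 arrays, and the median of an array lay between 5.40 and 5.45. No 2 arrays held identical values. For arrays, their number limits the precision.

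Probe sets were named through the platform annotation supplied with the values. 41097 probe sets had 1 gene symbol, 1801 had several, and 11777 were not listed there and are unnamed here. Symbols were compared with a gene table of assembly GRCh38.p14 through the gene identifiers. 41043 of the 41097 matched and 0 symbols needed an update. That table was used only for names and for the order of genes along chromosomes. Per gene, the probe set with the highest mean over all arrays was kept among those with 1 symbol, which left 19775 genes. No dim probe sets were removed. No probe set was assigned to BAP1 in the annotation used, so the level of the targeted transcript was not analysed here and the labels were not checked by it.

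Linear models were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) over all 9 arrays in 3 groups, with 6 residual and 4.33 prior degrees of freedom. Contrasts were each shRNA against shControl, shBAP1 #2 against shBAP1 #1, and the mean of both shRNAs against shControl. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 19775 genes were counted as changed, with no fold minimum. A gene changed the same way by both shRNAs passed this threshold in both comparisons with the same sign. Standard errors (SE) come from the fit, with n = 3 arrays per group.

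31 gene lists were tested with camera at its preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 31 lists, and again with a correlation estimated from the data. With the estimated correlation 0 lists passed in any of the contrasts, and 2 lists had an unadjusted p below 0.05 for the mean of both shRNAs. limma's fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, called 17 lists for that mean. List counts are given over all genes tested and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

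The groups, the tests, the gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined. The rule took the 12 raised and 12 lowered genes whose smaller absolute change over both shRNAs was largest among genes changed the same way by both and with a mean at or above the median of all probe set means (5.44). It added up to 4 members per list, those changed the same way by both with the largest mean change, or the 2 with the smallest p where none was. COX7C was included because it is known from work on BAP1, which may include the study of these arrays. The rule also took the 6 raised and 6 lowered genes with the largest difference between the shRNAs. Provisional symbols and some sex-linked genes were left unnamed. Of the 120 genes named by this rule, 72 have further probe sets, 45 are read by a probe set whose suffix marks probes shared between transcripts, and 10 of those carry the suffix for probes that match unrelated transcripts too.

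The model was tested on simulated data made from the real means and spreads. For shBAP1 #1 against shControl, 80.6% of 67 genes given a log2 change of 0.5 were recovered, and 100% of those given 1 or 2. The same shares at 0.5 were 89.6% of 134 genes for shBAP1 #2, 77.6% of 67 for genes changed the same way by both and 91.0% of 67 for the difference between the shRNAs. False calls made up 5.56%, 6.99%, 1.60% and 4.43% of all calls. The list test called the 1 shifted list and 0 of the others. Noise was drawn for each gene independently, so this does not show how often the list test calls falsely where genes of a list move together.

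Both comparisons share their control arrays. Unchanged groups were therefore simulated 100 times with shared controls that were simulated too, and the overlap of calls was also set beside that of independent lists. Alternatives were the replicate number as a block, a trended and robust variance model, fits of only the 2 groups compared, removal of dim probe sets, the mean of all probe sets of a gene, every probe set on its own, centring on the brighter probe sets, cyclic loess between arrays, a fold minimum of 1.5, array weights, ordinary least squares, and leaving out each array in turn.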

Results

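Expression was measured in 9 arrays of U2OS osteosarcoma cells held at the G1/S border, 3 each with shControl, shBAP1 #1 and shBAP1 #2. Arrays of 1 group correlated across probe sets with r between 0.995 and 0.997. Control arrays correlated with shBAP1 #1 arrays at 0.985 to 0.990 and with shBAP1 #2 arrays at 0.981 to 0.989, and arrays of the 2 shRNAs correlated with each other at 0.977 to 0.987. Replicate 1 of shBAP1 #2 stood nearer to the controls (mean r = 0.989) than replicates 2 and 3 (0.981 each). The difference between 3' and 5' probe sets of actin, a sign of RNA integrity and labelling, was 0.49 ± 0.02 log2 units in shControl (SD, n = 3), 0.40 ± 0.01 in shBAP1 #1 and 0.41 ± 0.04 in shBAP1 #2. For GAPDH it was -0.03 ± 0.02, -0.04 ± 0.01 and -0.04 ± 0.01. The actin difference was larger in every control array (0.47 to 0.51) than in any shBAP1 array (0.39 to 0.46). It thus separates shControl from both shRNAs, as the changes shared by both do, and whether it bears on them was not tested.

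The study asked which transcripts depend on BAP1, which removes ubiquitin from histone H2A and other substrates and binds the transcriptional cofactor HCF-1 and the factor YY1. A change seen with both shRNAs addresses that question more directly than a change seen with 1 of them, because each hairpin can have targets of its own. Knockdown of the BAP1 transcript itself was not analysed here.

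Both shRNAs lowered CCNE2, the cyclin E2 gene that drives entry into S phase, by similar amounts: the log2 change was -2.46 with shBAP1 #1 and -2.51 with shBAP1 #2 (SE 0.28 each, n = 3). PDGFRA, a receptor for platelet-derived growth factor, changed by -2.35 and -2.49, and CNN1, an actin-binding calponin of smooth muscle, by -2.03 and -2.66. On the other side, the lysyl oxidase gene LOX, whose product cross-links collagen, rose by 1.78 and 1.67, the metalloproteinase gene ADAM19 by 2.25 and 1.80, and the anti-apoptotic BCL2 relative BCL2A1 by 1.89 and 2.54. In all, 2315 of 19775 genes changed the same way with both shRNAs, 1230 higher and 1085 lower (limma, Benjamini-Hochberg adjusted p below 0.05 in each comparison).

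Among the other strongly lowered genes were LIN28B, an RNA-binding repressor of let-7 microRNA maturation (-1.91 and -2.00), the procollagen peptidase gene ADAMTS3 (-1.81 and -1.85), the small heat shock protein gene HSPB3 (-2.03 and -2.04), the carboxylesterase gene CES1 (-1.76 and -2.00) and the zinc finger gene ZNF367 (-1.86 and -2.01). SYTL5, of the synaptotagmin-like family, changed by -1.71 and -2.09, FAM111B by -1.57 and -1.93, RELL1 by -1.53 and -2.03, and the long noncoding RNA LUARIS by -2.15 and -1.96. Raised genes included the protease inhibitor gene SPINK6 (2.49 and 2.09), the long noncoding RNA GAPLINC (2.52 and 1.96), the collagen gene COL22A1 (2.34 and 1.67), the lymphatic growth factor gene VEGFC (1.68 and 1.51) and the microfibril gene MFAP5 (1.43 and 1.93). ENC1, which encodes an actin-associated kelch protein, rose by 1.5 and 1.58, SPG21 by 1.58 and 1.96, SLC66A3 by 1.44 and 2.09, and the p53 target TP53INP1 by 1.42 and 1.67. The means of HSPB3 and LUARIS with both shRNAs, of CES1 with shBAP1 #2 and of SPINK6 and GAPLINC in the controls lay below the median of all probe set means (5.44), where background limits the signal, so the sizes of these changes may be understated. For all 24 of these most changed genes, each of the 6 shBAP1 arrays lay beyond all 3 control arrays.

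**Figure D1:**
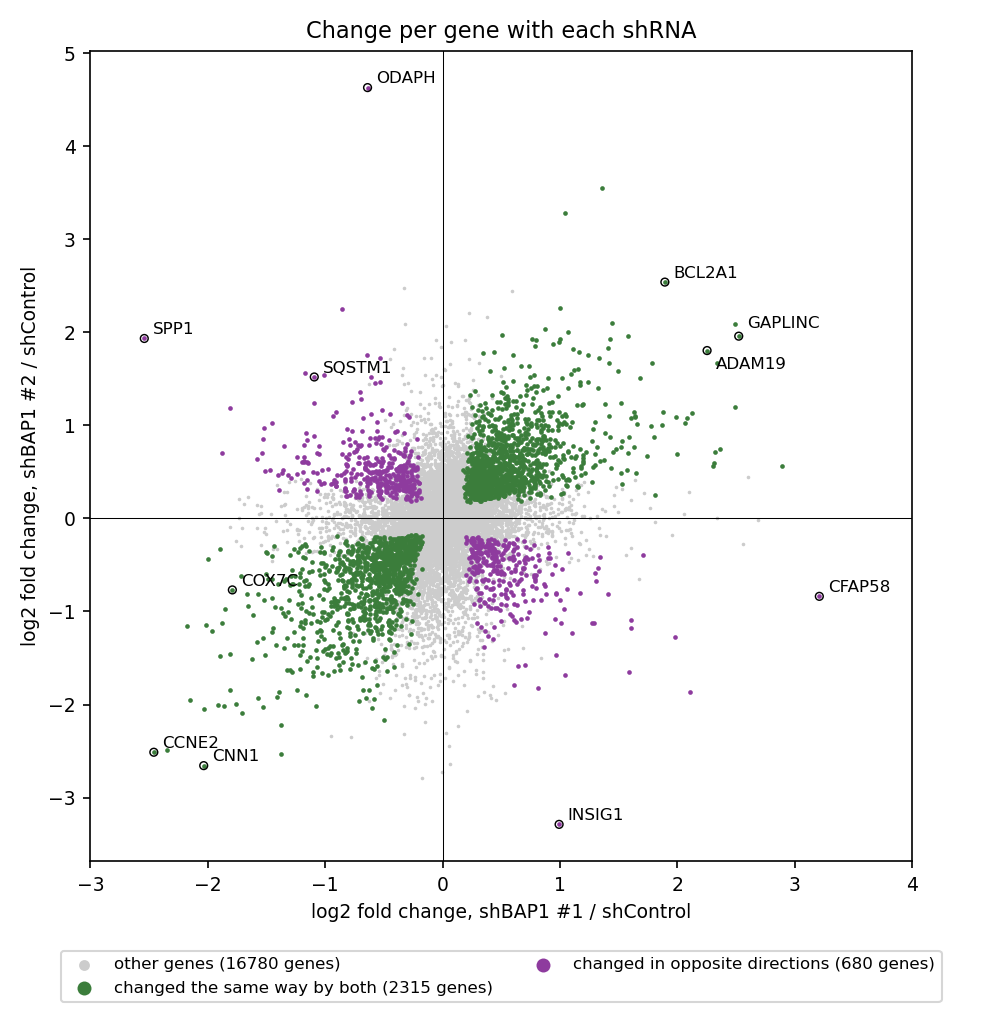
Log2 fold change against shControl with shBAP1 #1 (horizontal) and with shBAP1 #2 (vertical), 1 point per gene from the limma fit, with 2315 genes changed the same way by both in green, 680 changed in opposite directions in purple and the rest in grey. CCNE2 sits at -2.46 and -2.51, COX7C at -1.79 and -0.77, and SPP1 at -2.54 and 1.93.

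The overlap was larger than that of independent lists with the same numbers of calls, which would share 435 higher and 409 lower genes. It was not complete, since 680 of the 2995 genes changed by both shRNAs (22.7%) changed in opposite directions, where independent lists would give 844. Across genes, which are not independent replicates, the fold changes of the 2 shRNAs correlated at r = 0.328 (Spearman's rho = 0.317). Unchanged groups simulated with shared, likewise simulated controls gave r = 0.499, rho = 0.474 and 0 genes changed the same way. Their covariance of 0.00513 compares with an observed 0.0505, a difference of 0.0454. The simulated genes were independent noise, which leaves hardly any calls to share. A shift of many genes together in the real control arrays was not simulated. Part of the excess over independent lists may come from the shared controls, which at 3 arrays are too few to split.

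Genes of DNA replication and the G1/S transition fell with both shRNAs. Of 62 measured members, 38 were lower with both (40 adjusted over the list alone), 0 were higher with both and 2 changed in opposite directions. Besides CCNE2, the lowered members included SKP2, a ubiquitin ligase subunit that targets the inhibitor p27 (-1.24 and -1.84), POLE2, a subunit of DNA polymerase epsilon (-1.33 and -1.63), and GINS4 of the replicative helicase (-1.38 and -2.22). The list's median log2 change was -0.55 with shBAP1 #1 and -0.90 with shBAP1 #2, and in every shBAP1 array the list median lay below all 3 controls. Camera gave an adjusted p = 3.3e-20 for the mean of both shRNAs, and adjusted p = 0.51 with an estimated correlation, which was 0.669 for this list.

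Genes of homologous recombination and the DNA damage response fell as well, 15 of 38 with both shRNAs (17 adjusted over the list alone) and 1 higher with both. The checkpoint kinase gene CHEK1 changed by -1.38 and -0.96, the recombinase paralogue RAD51B by -1.18 and -1.09, the BRCA1-interacting helicase BRIP1 by -0.97 and -1.39, and the fork protection gene TIPIN by -0.85 and -1.54. Camera's adjusted p was 2.0e-12 for the mean of both, and adjusted p = 0.51 with an estimated correlation. With the mean of all probe sets per gene, RAD51B no longer passed the threshold for shBAP1 #1.

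Genes of G2 and mitosis separated the shRNAs: 38 of 44 members were lower with shBAP1 #2, and 6 were lower and 2 higher with shBAP1 #1 (the same counts adjusted over the list alone). The 6 lowered by both included the survivin gene BIRC5 (-1.29 and -1.08), the mitotic kinase gene CDK1 (-0.71 and -1.31) and the spindle-associated gene HMMR (-1.16 and -1.89). The list median was -0.19 with shBAP1 #1 and -1.09 with shBAP1 #2, and the 3 arrays of shBAP1 #2 stood at -0.58, -1.28 and -1.28, replicate 1 again nearest to the controls. Camera's adjusted p was 0.043 for shBAP1 #1 (adjusted p = 0.926 with an estimated correlation) and 1.8e-15 for shBAP1 #2 (adjusted p = 0.381 with an estimated correlation). The shBAP1 #1 call was lost in 5 of 15 other settings: cyclic loess, dim probe sets left out, and without shBAP1 #1 replicate 2, shControl replicate 1 or shControl replicate 3, with adjusted p up to 0.301. For the mean of both shRNAs the adjusted p was 5.0e-11, and adjusted p = 0.581 with an estimated correlation.

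**Figure D2:**
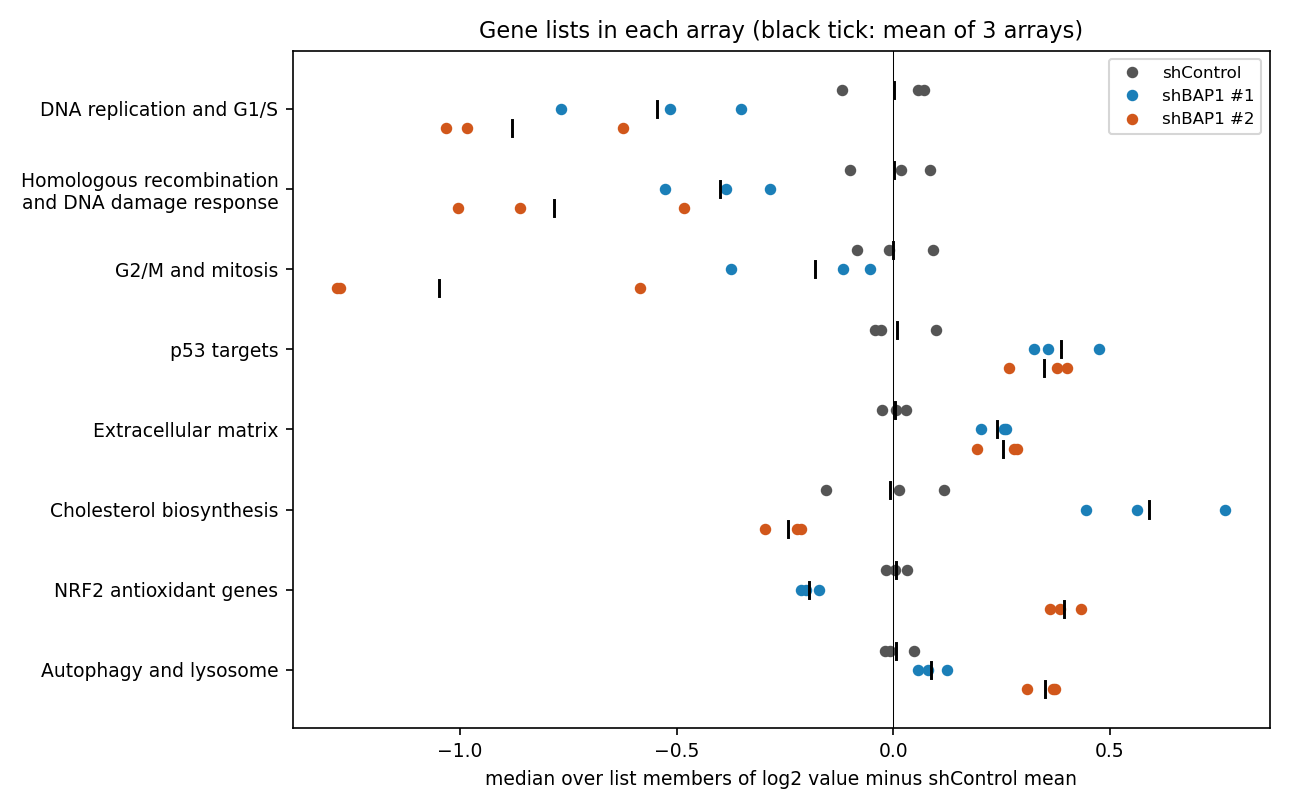
Median over the members of 8 gene lists of the log2 value minus the mean of the shControl arrays, 1 point per array, with a black tick at the mean of the 3 arrays of a group. The replication list lies at -0.35 to -0.77 with shBAP1 #1 and at -0.62 to -1.03 with shBAP1 #2, and the cholesterol list lies above all controls with shBAP1 #1 and below them with shBAP1 #2.

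Targets of p53 rose with both shRNAs: 13 of 28 members were higher and 1 lower with both (16 and 2 adjusted over the list alone). The death receptor gene TNFRSF10B rose by 1.09 and 1.55, PHLDA3, an inhibitor of AKT signalling, by 0.56 and 1.04, and the stress-inducible GADD45A by 0.54 and 1.19. Camera's adjusted p was 1.9e-06 for the mean of both shRNAs (adjusted p = 0.505 with an estimated correlation), and every shBAP1 array lay above all controls for this list. The call of GADD45A with shBAP1 #1 was lost in 2 of 9 fits that left out 1 array, reaching an adjusted p = 0.0616 at a log2 change of 0.44 without shControl replicate 1.

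Extracellular matrix genes rose too, 13 of 39 higher and 2 lower with both shRNAs (the same counts adjusted over the list alone). COL5A2, a chain of type V collagen, rose by 2.32 with shBAP1 #1 and 0.71 with shBAP1 #2, and the stromelysin gene MMP3 by 1.87 and 1.14. LOXL1, a relative of LOX, rose by 0.51 and 1.97. Camera's adjusted p for the mean of both was 2.6e-06, and adjusted p = 0.337 with an estimated correlation. Without shControl replicate 2 the adjusted p of LOXL1 for shBAP1 #1 was 0.0583 at a log2 change of 0.41, the highest of 9 such fits, of which 2 lost that call.

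In the list of adhesion and cytoskeleton genes, 6 of 31 members were higher and 1 lower with both shRNAs (9 and 1 adjusted over the list alone), 6 changed in opposite directions, and its smooth muscle genes went different ways. The smooth muscle actin gene ACTA2 rose by 2.08 and 1.07 and the focal adhesion gene PXN by 0.75 and 1.01, while CNN1 fell. The list's camera adjusted p for the mean of both was 0.00989 (adjusted p = 0.505 with an estimated correlation). Of the single shRNAs only shBAP1 #2 gave a call (median 0.38, against 0.08 and adjusted p = 0.166 with shBAP1 #1). The difference between the shRNAs was not called (median 0.12, adjusted p = 0.368). Autophagy and lysosome genes were called in the same direction for the mean of both (adjusted p = 0.0026 by camera, adjusted p = 0.524 with an estimated correlation), with 4 of 29 higher and 1 lower with both (6 and 1 adjusted over the list alone) and 5 changed in opposite directions. This list too was called by camera with shBAP1 #2 and not with shBAP1 #1 (adjusted p = 0.562, median 0.10, mean change 0.01). The list medians of all 3 shBAP1 #1 arrays nevertheless lay above all controls. Among them the lysosomal protective protein gene CTSA rose by 0.47 and 0.80 and the cholesterol carrier NPC2 by 0.70 and 0.43, whereas ATP6V1A, a subunit of the lysosomal proton pump, changed by -0.77 and -1.32. Epithelial markers were lower, 3 of 15 with both shRNAs (3 adjusted over the list alone), with KRT18 at -0.63 and -0.87 and EPCAM at -0.54 and -0.64. Their camera adjusted p was 0.00989, and adjusted p = 0.337 with an estimated correlation.

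COX7C, which encodes a subunit of cytochrome c oxidase and is known as a gene bound by BAP1 and its partners, was lower with both shRNAs: -1.79 ± 0.18 (SE, n = 3) with shBAP1 #1 and -0.77 ± 0.18 with shBAP1 #2. Its adjusted p in limma after Benjamini-Hochberg adjustment was 5.1e-05 and 0.0060, and the changes differed from each other by 1.02 (adjusted p = 0.0010). Its probe set carries the suffix for probes that also match unrelated transcripts. COX7C was chosen as a gene known from work on BAP1. That work may include the study of these arrays, so the fall of COX7C is not an independent check. Of 70 measured genes of oxidative phosphorylation, 6 were higher and 4 lower with both shRNAs (7 and 5 adjusted over the list alone), and camera did not call the list (adjusted p = 0.819). NDUFA1 rose by 0.87 and 0.71, while UQCRC2 changed by -0.43 and -0.90 and was not called for shBAP1 #1 with the mean of its probe sets.

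Genes of BAP1's protein partners were not called as a list (camera adjusted p = 0.858, 1 of 14 higher with both and 0 lower, the same adjusted over the list alone). The 1 member was OGT, the O-GlcNAc transferase, at 0.32 and 0.25. Its calls were lost in 2 and 6 of 9 fits that left out 1 array, with adjusted p up to 0.0618 without shBAP1 #1 replicate 2 (0.27) and 0.138 without shControl replicate 3 (0.18). Of 26 Polycomb group genes, which encode chromatin repressors including the complex that ubiquitinates histone H2A, 2 were higher and 4 lower with both (2 and 4 adjusted over the list alone; camera adjusted p = 0.858). SUZ12, a core subunit of Polycomb complex 2, changed by -0.82 and -0.84, and CBX6 rose by 0.42 and 0.61. PCGF5 (-1.5 and -0.60) and EED (-0.55 and -0.81) each have another probe set called the opposite way with shBAP1 #1, and the mean of the probe sets of EED was 0.20 there. For this list with shBAP1 #1 the median (0.14) and the mean (-0.01) differed in sign. HOX genes, classical targets of Polycomb repression, gave 1 higher and 1 lower of 28 (1 and 1 adjusted over the list alone; camera adjusted p = 0.383), with HOXB2 at 0.55 and 0.35.

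Against shControl, shBAP1 #1 changed 5058 genes, 2574 higher and 2484 lower, of which 869 and 960 changed at least 1.5-fold. Cholesterol biosynthesis stood out with this shRNA: 11 of 18 members rose and 1 fell (12 and 2 adjusted over the list alone), with a list median of 0.61. STARD4, a sterol carrier, rose by 1.08, the sterol oxidase gene MSMO1 by 0.96, SQLE, which encodes squalene epoxidase, by 0.88, and LSS, the lanosterol synthase gene, by 0.84. These 4 were chosen after their values were seen. Camera's adjusted p was 5.9e-05 (adjusted p = 0.586 with an estimated correlation). The member that fell was IDI1 (-0.41), whose probe set carries the suffix for probes that match unrelated transcripts.

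Other lists called with shBAP1 #1 were replication (adjusted p = 1.5e-12, and adjusted p = 0.586 with an estimated correlation), homologous recombination (4.0e-06, and adjusted p = 0.609 with an estimated correlation), p53 targets (4.0e-06, and adjusted p = 0.407 with an estimated correlation) and extracellular matrix (5.9e-05, and adjusted p = 0.407 with an estimated correlation). NRF2 antioxidant genes were lower (median -0.19, adjusted p = 0.00156, and adjusted p = 0.407 with an estimated correlation), as 9 of 18 fell and 1 rose (11 and 1 adjusted over the list alone). The endoplasmic reticulum chaperone list was higher (median 0.16, adjusted p = 0.0429, and adjusted p = 0.674 with an estimated correlation), with CRELD2 at 0.73 and 7 of 20 members higher against 1 lower (8 and 1 adjusted over the list alone). That call was lost in 6 of 15 other settings, with dim probe sets left out and without shBAP1 #1 replicate 1 or 2, shBAP1 #2 replicate 1, or shControl replicate 1 or 3, at adjusted p up to 0.172. Cytosolic ribosomal protein genes were slightly lower (median -0.07, adjusted p = 0.00455, and adjusted p = 0.586 with an estimated correlation), 10 of 50 falling (9 adjusted over the list alone) and 0 rising. Mitochondrial ribosome genes (adjusted p = 0.0187, and adjusted p = 0.701 with an estimated correlation) and epithelial markers (0.0394, and adjusted p = 0.407 with an estimated correlation) were called lower. Of these, the first was lost with dim probe sets left out and without shControl replicate 3, at up to 0.0918, and the second without shBAP1 #1 replicate 2 or shControl replicate 1, at up to 0.0776.

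Against shControl, shBAP1 #2 changed 6600 genes, 3341 higher and 3259 lower, of which 1110 and 1568 changed at least 1.5-fold. Besides the cell cycle lists above, NRF2 antioxidant genes rose with this shRNA: 12 of 18 were higher and 3 lower (13 and 3 adjusted over the list alone), with a median of 0.42. SRXN1, which encodes sulfiredoxin, rose by 1.24, AKR1C1, an aldo-keto reductase gene, by 0.94, and NQO1, a quinone reductase gene, by 0.40, while PRDX1, a peroxiredoxin gene, fell by 1.13. These 4 were chosen after their values were seen. Camera's adjusted p was 0.00134 (adjusted p = 0.356 with an estimated correlation).

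Autophagy and lysosome genes had 19 of 29 members higher and 3 lower with shBAP1 #2 (20 and 3 adjusted over the list alone; median 0.35, adjusted p = 2.3e-04, and adjusted p = 0.381 with an estimated correlation). NF-kappaB and inflammatory genes had 12 of 23 higher and 1 lower (12 and 3 adjusted over the list alone; median 0.33, adjusted p = 0.00134, and adjusted p = 0.381 with an estimated correlation). Of the adhesion genes, 17 of 31 were higher and 4 lower (20 and 4 adjusted over the list alone; adjusted p = 7.1e-04, and adjusted p = 0.356 with an estimated correlation). Cholesterol biosynthesis genes were lower, 8 of 18 falling and 0 rising (9 and 0 adjusted over the list alone; median -0.23, adjusted p = 6.1e-04, and adjusted p = 0.556 with an estimated correlation). Replication (adjusted p = 1.6e-18, and adjusted p = 0.381 with an estimated correlation), homologous recombination (5.5e-12, and adjusted p = 0.381 with an estimated correlation), p53 targets (5.0e-04, and adjusted p = 0.381 with an estimated correlation) and extracellular matrix (6.1e-04, and adjusted p = 0.381 with an estimated correlation) were called in the directions given above. The lower call of epithelial markers (0.0224, and adjusted p = 0.356 with an estimated correlation) was lost with dim probe sets left out and without shBAP1 #2 replicate 1, at adjusted p up to 0.105.

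The direct comparison of the 2 shRNAs gave 6860 genes that differed, 3382 higher and 3478 lower with shBAP1 #2 than with shBAP1 #1. INSIG1, the sterol-regulated anchor of the SREBP pathway, was at 0.99 with shBAP1 #1 and -3.29 with shBAP1 #2, a difference of -4.28 (SE 0.21, n = 3; limma adjusted p = 1.1e-06 after Benjamini-Hochberg adjustment). SPP1, the bone matrix gene for osteopontin, was at -2.54 and 1.93, and SQSTM1, which encodes the autophagy receptor p62, at -1.09 and 1.52. ODAPH, an enamel matrix gene, was at -0.64 and 4.63, HPCAL4, of the neuronal calcium sensor family, at -0.33 (not past the threshold) and 2.47, and ABRACL at -1.81 and 1.18. RNA45SN5, a ribosomal RNA precursor gene, was at -1.18 and 1.56. INSIG1 with shBAP1 #2, ODAPH with shBAP1 #1, and HPCAL4 with shControl and shBAP1 #1 had means below the median of all probe set means (5.44), so the sizes of their changes are limited by background.

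Genes lower with shBAP1 #2 than with shBAP1 #1 also included CFAP58 (3.21 and -0.84) and BBOF1 (1.98 and -1.28), both genes of cilia and flagella, the metalloproteinase gene ADAMTS6 (1.58 and -1.65), TMEM71 (1.61 and -1.18) and SYNE1, a nuclear envelope spectrin gene (2.11 and -1.86, SE 0.60). The mean of BBOF1 with shBAP1 #2 was also below the median of all probe set means. For SYNE1, single shRNA calls were lost in 3 and 4 of 9 fits that left out 1 array, with adjusted p up to 0.0932 without shControl replicate 2 (1.78) and 0.136 without shBAP1 #2 replicate 2 (-1.42). For CFAP58 the shBAP1 #2 call was lost in 7 of those 9, at an adjusted p up to 0.159 without shBAP1 #2 replicate 3 (-0.65).

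Cholesterol biosynthesis and NRF2 lists moved in opposite directions with the 2 shRNAs, and for both the difference itself was called. The cholesterol list differed by a median of -0.89 (camera adjusted p = 5.3e-09, and adjusted p = 0.683 with an estimated correlation), with 16 of 18 members lower with shBAP1 #2 and 0 higher. INSIG1, SREBF2, HSD17B7 and DHCR7 changed with both shRNAs in opposite directions. The NRF2 list differed by 0.63 (adjusted p = 1.1e-05, and adjusted p = 0.253 with an estimated correlation), with 14 of 18 higher and 3 lower, and its 7 members changed oppositely by both were AKR1C1, SLC7A11, NQO1, ME1, GSR, OSGIN1 and FTL. Members other than INSIG1 were named after their values were seen.

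**Figure D3:**
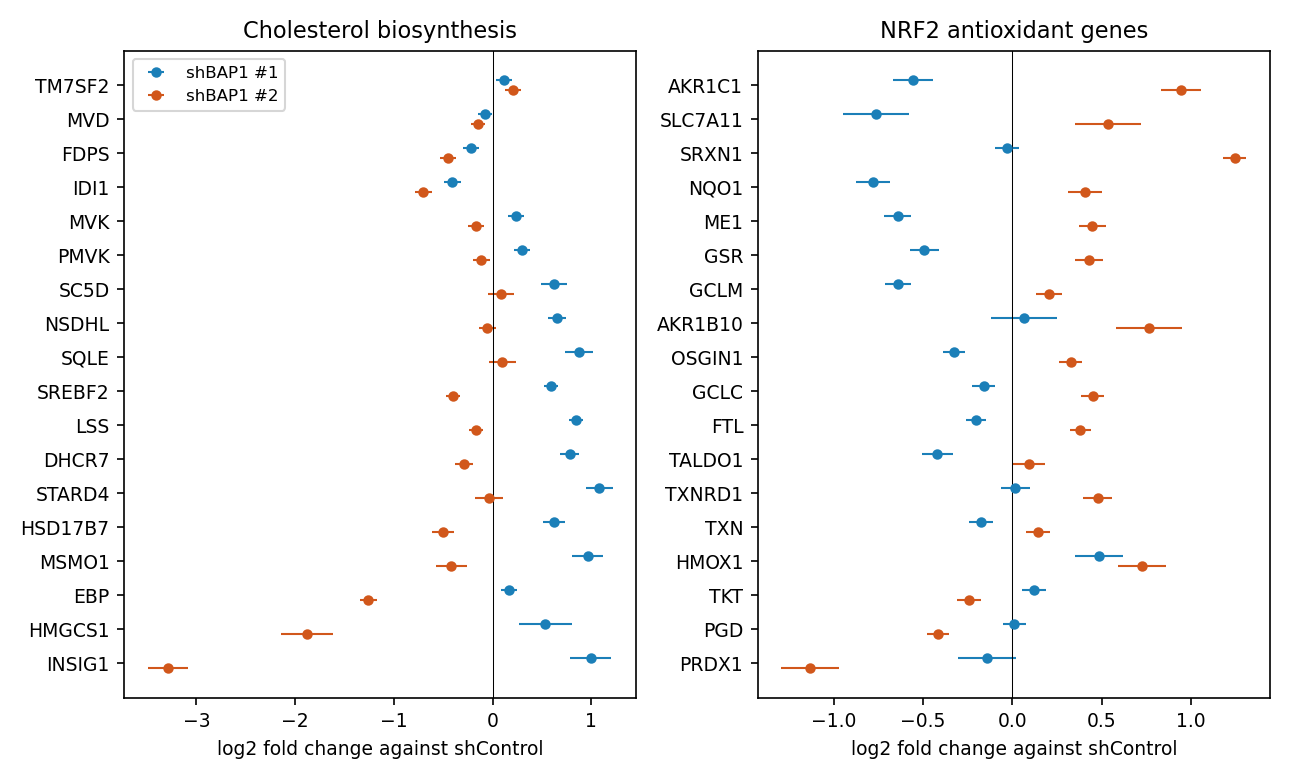
Log2 fold change against shControl of the 18 measured members of each of the cholesterol biosynthesis and NRF2 lists with shBAP1 #1 (blue) and shBAP1 #2 (orange), as estimates with bars of 1 SE from the limma fit (n = 3 arrays per group). INSIG1 stands at 0.99 and -3.29, and NQO1 at -0.78 and 0.40.

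Other lists whose difference was called were G2 and mitosis (median -0.96, camera adjusted p = 1.5e-09, and adjusted p = 0.683 with an estimated correlation), replication (-0.28, 0.00508, and adjusted p = 0.883 with an estimated correlation) and homologous recombination (-0.33, 0.00596, and adjusted p = 0.871 with an estimated correlation), all lower with shBAP1 #2. Chaperones of the endoplasmic reticulum (-0.36, 0.00453, and adjusted p = 0.683 with an estimated correlation) and the tricarboxylic acid cycle (-0.17, 0.0291, and adjusted p = 0.683 with an estimated correlation) were also lower with shBAP1 #2. NF-kappaB genes (0.40, 0.00453, and adjusted p = 0.683 with an estimated correlation), autophagy and lysosome genes (0.41, 0.016, and adjusted p = 0.683 with an estimated correlation), proteasome genes (0.10, 0.0237, and adjusted p = 0.802 with an estimated correlation) and apoptosis regulators (0.12, 0.026, and adjusted p = 0.521 with an estimated correlation) were higher. The osteoblast gene RUNX2 rose with shBAP1 #1 (1.20) and stood at 0.03 with shBAP1 #2 (adjusted p = 0.93 in limma), where its sign turned in 5 other settings, and ALPL, the alkaline phosphatase gene, rose with shBAP1 #2 (1.18) and stood at 0.24 with shBAP1 #1 (adjusted p = 0.14), its means with shControl and shBAP1 #1 being below the median of all probe set means. The differences were -1.17 and 0.94, each past the threshold.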

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

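The test of 1 response at 2 strengths was chosen only after the result was seen, and the scaling test and the counts over other splits were planned.

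Cholesterol biosynthesis genes differed between the shRNAs by a median log2 value of -0.89 and NRF2 antioxidant genes by 0.63, each list being called in opposite directions by the 2 shRNAs with camera's preset correlation. With an estimated correlation neither was called: adjusted p = 0.586 and adjusted p = 0.556 with an estimated correlation for cholesterol with shBAP1 #1 and #2, and adjusted p = 0.407 and adjusted p = 0.356 with an estimated correlation for NRF2. In all, 680 genes changed in opposite directions with a difference past limma's threshold. Of the 120 genes named by the rule, those whose changes with the 2 shRNAs each passed the threshold, with opposite signs, and whose difference passed it too were ODAPH (5.27), SPP1 (4.47), ABRACL (3.0), RNA45SN5 (2.74) and SQSTM1 (2.61), higher with shBAP1 #2, and INSIG1 (-4.28), CFAP58 (-4.05), SYNE1 (-3.97), BBOF1 (-3.26), ADAMTS6 (-3.23) and TMEM71 (-2.79), lower with it, each a difference in log2 units. Outside the genes named by the annotation, 315 of 13522 probe sets with no gene or several genes changed the same way by both shRNAs, 150 higher and 165 lower.

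For the opposite lists, centring on the brighter probe sets and cyclic loess were tried. Under both, the list medians of the 2 shRNAs kept opposite signs and differed by at least 0.58. These scalings altered little after RMA, which had forced the same distribution on every array. The median change of all genes with shBAP1 #2 was 0.016 as deposited, 0.046 under centring and 0.001 under cyclic loess. Scaling differences left after RMA are thus argued against, while an effect of RMA itself was not tested. A single response present at 2 strengths is also argued against, because it would leave opposite calls at the level of false calls, and 22.7% of the genes changed by both went opposite ways. Targets particular to each hairpin, differences between the cultures that arose during selection, and responses that depend on how far BAP1 was lowered stay open, and none of these was tested.

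Other splits of the samples bear on the counts only in part. For 2 groups of 3 arrays there are 10 splits, too few for a share under 0.05: the real split gave 5276 genes for shBAP1 #1 against shControl, 6308 for shBAP1 #2 and 6444 between the shRNAs in fits of those 6 arrays, only 1 split of each 10 was as large, and the highest other split gave 0. Of 100 splits of the 9 arrays into 3 groups, 4 gave at least the 2315 genes changed the same way by both. The real split was among these 4, and 2774 was the highest of the others. All 4 kept 3 arrays of 1 study group together as the control, as 8 of the 100 splits did. The highest count among splits that did not was 0, which points to a structure of the samples by study group. The share of 4 in 100 therefore follows how often such splits were drawn, and cannot exclude chance for this count. For the mean of both shRNAs, 3 of 100 splits called at least the real 11 lists, with 13 the highest of the others, a count reached by a split whose control mixed study groups.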

How the results depend on the processing

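All alternatives were planned, and those for the level of BAP1 were not run, because no probe set was assigned to it. Counts changed by over 1.5 times under 2 settings that alter what is counted. With every probe set on its own they were 8947 for shBAP1 #1, 11873 for shBAP1 #2, 3890 the same way by both and 12436 between the shRNAs, out of 41097. With a fold minimum of 1.5 they were 1829, 2678, 606 and 2949. Leaving out 1 array gave 3912 to 5571, 5456 to 6885, 1682 to 2460 and 5793 to 7080 genes, 9 to 11 lists, and a correlation of fold changes of 0.302 to 0.347. Without shBAP1 #2 replicate 1 alone the 4 counts were 5571, 6885, 2460 and 7080. The correlation was 0.351 with the mean of all probe sets of a gene. An estimated correlation left 0 called lists and fry gave 17.

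Over the 3 groups the replicate number was not taken to pair the samples: same-numbered arrays had deviations from their group means that correlated at -0.21 to 0.22, with 4 of 9 pairs over 0.1. The 3 pairs of shControl with shBAP1 #1 were all over 0.1 (0.113, 0.203 and 0.216), so a pairing of these groups alone is not excluded, and 6 of 9 arrays correlated best with their own number, a hint from the data and not from the design. With the replicate number as a block the counts were 4988, 6548, 2274 and 6787, with 11 lists. Of the values of named genes, 5 changed side of the threshold under the block (RPL10A, RPL12 and MRPL10 with shBAP1 #1, ID3 and CFAP58 with shBAP1 #2), and Neural markers passed it for shBAP1 #1 (camera adjusted p = 0.0358 with the block and 0.0533 without, and without the block adjusted p = 0.407 with an estimated correlation), while no other list call changed.

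Of 4780 alternatives for 252 values of named genes, 4579 kept direction and side of the threshold, 191 fell short of it, 4 newly passed it and 6 reversed. Ordinary least squares, which borrows no spread from other genes, lost the most of these calls, 29 of 252. EED with shBAP1 #1 turned to 0.20 with the mean of its probe sets, which were called in opposite directions. RUNX2 with shBAP1 #2, near 0 throughout, turned to -0.00728 with the mean of its probe sets and -0.10 with array weights, ranged from -0.06 to 0.13 on leaving out 1 array (below 0 in 3 of 9 fits, -0.00647 without shControl replicate 2, -0.0386 without shControl replicate 3 and -0.0587 without shBAP1 #2 replicate 1), and the cause was not tested. No other scaling moved the median of all genes by over 0.1, nor the share of higher calls by over 10 percentage points. Signal over background limits the dim genes: 14 of 120 named genes had a group mean below the median of all probe set means, and 4 of them with the mean of all arrays below it (HOXB8, ALPL, STMN2 and H2BC11) have no value with dim probe sets left out.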

Other observations

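The tests with the G2/M list as a covariate, read for each shRNA, and both tests on shBAP1 #2 replicate 1 were chosen only after the result was seen, and the scaling and neighbour tests were planned.

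Several lists were not called for the mean of both shRNAs while single members moved with each. Among glycolysis and hypoxia genes, 4 of 32 were higher and 2 lower with both (5 and 2 adjusted over the list alone; camera adjusted p = 0.902), and the collagen prolyl hydroxylase gene P4HA2 rose by 1.03 and 1.04, while the histone demethylase gene KDM3A changed by -0.53 and -0.50. In the integrated stress response, SESN2, a stress-induced inhibitor of mTORC1, rose by 0.85 and 0.58 and PSAT1 of serine synthesis changed by -1.45 and -1.18 (3 higher and 2 lower of 27, the same adjusted over the list alone; adjusted p = 0.383). The heat shock regulator HSF1 rose by 0.59 and 1.11 and the small heat shock gene CRYAB changed by -1.38 and -2.54 (1 and 1 of 13, the same adjusted over the list alone; adjusted p = 0.838). Among neural markers, the neurofilament gene NEFL rose by 1.64 and 1.10 and SCG5 by 0.73 and 1.64, while SNAP25 changed by -0.65 and -0.75 (4 and 2 of 18, the same adjusted over the list alone; adjusted p = 0.325). The interferon-inducible TRIM22 rose by 0.99 and 1.32 in a list with 1 higher and 0 lower of 39 (the same adjusted over the list alone; adjusted p = 0.768).

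Genes of the RNA interference machinery, read because shRNAs use it, gave 2 higher and 2 lower of 12 (the same adjusted over the list alone; adjusted p = 0.819), with TNRC6C at 1.14 and 1.22 and TARBP2 at -0.26 and -0.68. Apoptosis regulators gave 4 higher and 3 lower of 30 (the same adjusted over the list alone; adjusted p = 0.819), with BAK1 at 0.62 and 0.86. Proteasome genes gave 2 and 1 of 27 (the same adjusted over the list alone; adjusted p = 0.854), with PSMB5 at 0.54 and 0.80. For the TGF-beta response, 1 and 1 of 20 (2 and 1 adjusted over the list alone; adjusted p = 0.519), TGFBR2 rose by 0.75 and 0.50. In the tricarboxylic acid cycle, OGDH rose by 0.88 and 0.71 (1 and 0 of 19, the same adjusted over the list alone; adjusted p = 0.66). Replication-dependent histones gave 1 and 1 of 35 (0 and 1 adjusted over the list alone; adjusted p = 0.819), with H2BC11 at -0.65 with each shRNA. Osteoblast markers gave 0 of 11 (0 adjusted over the list alone; adjusted p = 0.18) and blood cell markers 1 and 1 of 13 (the same adjusted over the list alone; adjusted p = 0.942).

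Mitochondrial ribosome genes were called lower for the mean of both shRNAs (adjusted p = 0.0133, and adjusted p = 0.726 with an estimated correlation), with 6 lower and 4 higher of 69 (7 and 4 adjusted over the list alone). MRPS9 changed by -0.83 and -0.87 and MRPL45 by 0.89 and 1.4. That call was lost with dim probe sets left out and without shControl replicate 3, at adjusted p up to 0.101. Cytosolic ribosomal protein genes were called lower (adjusted p = 0.0207, and adjusted p = 0.581 with an estimated correlation; 3 of 50 lower with both, 1 adjusted over the list alone), which was lost under centring on the brighter probe sets, cyclic loess and removal of dim probe sets, at adjusted p up to 0.0744. NF-kappaB genes were called higher for the mean of both (adjusted p = 0.0352, and adjusted p = 0.6 with an estimated correlation; 1 of 23 higher and 0 lower with both, 1 and 1 adjusted over the list alone, and 3 in opposite directions), lost with dim probe sets left out and without shBAP1 #2 replicate 3 or shControl replicate 3, at adjusted p up to 0.101. Of the single shRNAs only shBAP1 #2 gave an NF-kappaB call (median 0.33, against -0.00738 and adjusted p = 0.872 with shBAP1 #1), and with shBAP1 #2 neither the mitochondrial (adjusted p = 0.212) nor the cytosolic ribosome list (adjusted p = 0.418) was called. The difference between the shRNAs was called for NF-kappaB genes (adjusted p = 0.00453, and adjusted p = 0.683 with an estimated correlation) and not for these ribosome lists (adjusted p = 0.724 and 0.269).

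The replication and repair lists were lower with both shRNAs. Scaling differences left after RMA are argued against, since under 2 other scalings the median of the replication list stayed at -0.55 or below with each shRNA. Those scalings altered little after RMA, and an effect of RMA itself was not tested. Fewer cells in G2 and mitosis as the whole cause is argued against for shBAP1 #1 only as far as the G2/M list mean stands for such cells. With that mean of each array as a covariate the replication list mean still changed by -0.43, with a 95% interval of -0.64 to -0.23. The upper bound remained below 0 on leaving out each array, at most -0.12. All groups shared 1 slope, which was 0.72, and 1.23 without shBAP1 #2 replicate 1, where the change was -0.33. A list mean that tracks these cells poorly would adjust too little. For shBAP1 #2 the same fit gave -0.16 with an upper bound of 0.28, and 0.52 without replicate 1 of that shRNA, and this cause cannot be told apart from a direct effect, because the G2/M list fell most in the same arrays. A direct effect of BAP1 loss and effects particular to each hairpin, the control hairpin included, stay open and untested. The completeness of the arrest in each culture was not measured here.

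Replicate 1 of shBAP1 #2 lay nearer to the controls than replicates 2 and 3. Unaffected cells in that culture could explain it if all lists shared 1 proportion of control-like signal, and that proportion was 33.0% for the cell cycle lists and 22.8% for the other lists called with shBAP1 #2, a difference of 10.2 percentage points on the linear scale (95% interval over genes 4.88 to 15.6). The difference was 26.4 points on the log2 scale, so its size depends on the scale, the linear scale was chosen after the log2 values were seen, replicates 2 and 3 stand in for the pure state, and unaffected cells cannot be told apart from a culture with less cell cycle change. The difference between 3' and 5' actin probe sets was 0.456 in replicate 1, against 0.388 and 0.391 in replicates 2 and 3 and 0.468 to 0.507 in the controls. A technical source was not tested. A share of shBAP1 #1 cells would be 43.3% by the cell cycle lists and 3.27% by the cholesterol and NRF2 lists. The difference was 40.0 points (95% interval over genes 30.2 to 48.8), and 49.7 on the log2 scale. Both intervals resample genes as if they were independent, although genes of a list move together, and do not measure the spread between cultures. The cholesterol and NRF2 lists were chosen because they differed between the shRNAs in these same arrays. With 1 array, a share of shBAP1 #1 cells is therefore not decided.

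Copy number drift between the cultures was examined through neighbouring genes. Fold changes of genes 20 apart along the chromosomes correlated by at most 0.0206 (Spearman, 12721 genes), within the range of 1000 permuted gene orders, so drift over wide regions as a common source of change was not seen, while direct neighbours correlated at 0.0312 for the difference between the shRNAs, above the permuted maximum of 0.0268, and within the permuted range for shBAP1 #1 (0.0240, maximum 0.0273) and shBAP1 #2 (0.0249, maximum 0.0279) against shControl.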
